A study of Mus musculus with 15 samples.

How the data were processed

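RNA from 15 samples of sorted germinal centre B cells was amplified and hybridised to whole-transcript arrays, 1 sample per array, per the labels' protocols. The authors deposited 1 table of log2 values for 28853 probe sets, made with RMA, which corrects background, normalizes by quantiles and summarises probes, per the submitters' processing notes, which also name genome build mm8. The software and its version are not given in the sources used here. RMA compresses the differences of dim probe sets, and amplification of small amounts of RNA adds spread between samples. The table has no detection calls, so no gene was called absent.

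Groups and replicate numbers were taken from the sample titles. Probe sets were named from the platform annotation: 21789 had 1 gene, 1621 had several and 5443 had none there. Of the former, 21698 matched a gene of the reference table by Entrez ID and 0 symbols changed. Probe sets with several genes or none were left out, and of the 999 genes with more than 1 probe set the one with the highest mean was kept, which left 19938 genes. No filter on dim genes was used. The highest correlation between any pair of arrays was 0.992, and no array was counted as a repeat of another.

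Limma 3.58.1 (lmFit and eBayes) in R 4.3.3 fitted 4 group means to all 15 arrays, with 11 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists of a comparison, with camera at an estimated correlation and fry beside it. Fry, which asks whether the genes of a list move one way on balance, passed 6 lists between zones, 0 for affinity in the light zone, 1 in the dark zone and 0 for the interaction. Of 1112 list entries, 93 were not matched and are not analysed here. Figures were drawn with matplotlib 3.10.9.

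The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, per comparison, the 10 largest changes in each direction among genes that passed and whose groups did not overlap, without predicted genes, receptors of smell, small RNAs and antigen receptor segments, then up to 2 passing genes per list and direction, and a set of genes of which 15 were measured. Genes with a value in the text that did not pass over all genes, other than those of that set, were chosen after their values were seen. Not every gene of that set is printed in each comparison, so the printed ones do not show the set as a whole.

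The experiment code in the descriptions was read as a shared day of sorting. It takes 5 forms, and codes that differed only in their last number were merged into 4. That merge joins the dark zone and light zone forms of code B, so it runs along the zone comparison, and whether they are 1 experiment is not known. Arrays of different groups with the same code deviated together, with a mean correlation of 0.288 over 21 pairs, of which 16 were above 0.1. For different codes the mean was -0.0821, with 21 of 63 pairs above 0.1, and for the same title number it was 0.227. DZ_high replicates 1 and 4 deviated, on average, more with arrays of another code than with those of their own. The title number does not follow the code for experiments C and D. The fit with the code as a block is given beside the printed results that it changed.

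Alternatives changed the normalization, the filter, the rows tested, the probe set rule, the variance model, array weights, the block, the arrays included and the threshold. Leaving out the 2 low-affinity arrays of experiment D, or all of that experiment, was chosen after seeing the data. The steps were tested on simulated data with 200 changed genes among 19938, some changed by 1 on the log2 scale and the others by 2. Of those changed by 1, 87.2% were recovered between zones over both affinities and 67.2% for affinity in the light zone. The shares were 73.8% in the dark zone and 38.6% for the interaction. Noise was drawn independently for each array, without a shared deviation of an experiment or RNA of other cells. The shares hold for such data and can be lower in the real arrays.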

Results

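Gene expression was measured by whole-transcript microarray in germinal centre B cells sorted from mouse spleen 10 days after immunization. The cells were SwHEL B cells, whose knocked-in receptor binds hen egg lysozyme, recovered from recipient mice immunized with red blood cells carrying a lysozyme mutant. They were separated into light zone cells, with high CD86 and low CXCR4, and dark zone cells, with the opposite pattern, and each zone into cells of high and of low affinity. There were 4 arrays of high-affinity dark zone cells (DZ_high), 4 of low-affinity dark zone cells (DZ_low), 3 of high-affinity light zone cells (LZ_high) and 4 of low-affinity light zone cells (LZ_low). The sample descriptions carry 5 experiment codes, merged here into 4, A to D. Code B is written differently for dark zone and light zone arrays, and no LZ_high array came from experiment D. The values were RMA values on the log2 scale, with array medians between 5.57 and 5.74. All 4 groups entered 1 limma fit over 19938 genes, and every error given for a change is its standard error in that fit. The number of arrays limits the precision, and p-values measure the spread between these samples, since the labels do not say whether each came from separate mice.

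The first comparison asked how light zone and dark zone cells differed, over both affinities. In limma, 17 genes were higher and 14 lower in light zone cells at an adjusted p under 0.05. Fcer2a, which encodes the IgE receptor CD23, rose by 1.69 ± 0.13 on the log2 scale, a 3.22-fold difference (adjusted p = 9.56e-05). It was higher in 7 of 7 pairs from the same merged experiment, of which 2 join the differently written forms of code B. The transcription factor gene Hhex rose by 1.92 ± 0.25 and the immediate early gene Egr2 by 1.43 ± 0.17. The surface molecule genes Tnfsf9, encoding 4-1BB ligand, Cd83 and Cd72 rose by 1.55 ± 0.19, 1.49 ± 0.18 and 1.37 ± 0.17. Aldoc, a glycolytic aldolase, rose by 1.36 ± 0.17. Further increases were those of the sphingosine phosphate receptor gene S1pr3 by 1.23 ± 0.16, Batf by 0.91 ± 0.14, and Nfkbia, which encodes an inhibitor of NF-kappaB, by 0.91 ± 0.13. On the dark zone side, the light zone value of Selenop, encoding selenoprotein P, fell by 1.57 ± 0.23, a 2.96-fold difference (adjusted p = 0.0101). Otub2 fell by 1.26 ± 0.19, Serinc5 by 1.20 ± 0.16, Scn11a by 1.08 ± 0.19, Myl4 by 1.06 ± 0.15 and Nt5e, encoding CD73, by 0.92 ± 0.17. The chromatin remodelling gene Smarca4 fell by 0.87 ± 0.15, and Hmces, which encodes a sensor of abasic DNA sites, fell by 0.82 ± 0.10. Lgr5 fell by 0.66 ± 0.12 and Ccdc190 by 0.63 ± 0.10. Each of these genes differed in its direction in 7 of 7 pairs. For genes taken by the rule that groups do not overlap, this was fixed by the choice and adds no evidence. The genes of the sort markers are no finding between zones. Cd86, which is counted among the 17, was higher by 1.04 ± 0.11. The Cxcr4 change was -0.69 ± 0.16 (adjusted p = 0.152, or 0.0386 with the experiment code as a block). With that block, 90 genes passed, 50 higher and 40 lower, and all 31 were among them. The block merges the dark zone and light zone forms of code B, so these counts rest on that merge. With each array centred on its median, 22 passed, 15 higher and 7 lower. The count was 19 without DZ_low replicate 1, 20 without LZ_high replicate 1, 18 without LZ_high replicate 2 and 20 without LZ_low replicate 2. Scn11a, Nt5e, Smarca4, Lgr5 and Ccdc190 passed in at most 4 of the 15 fits that left out 1 array.

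**Figure D1:**
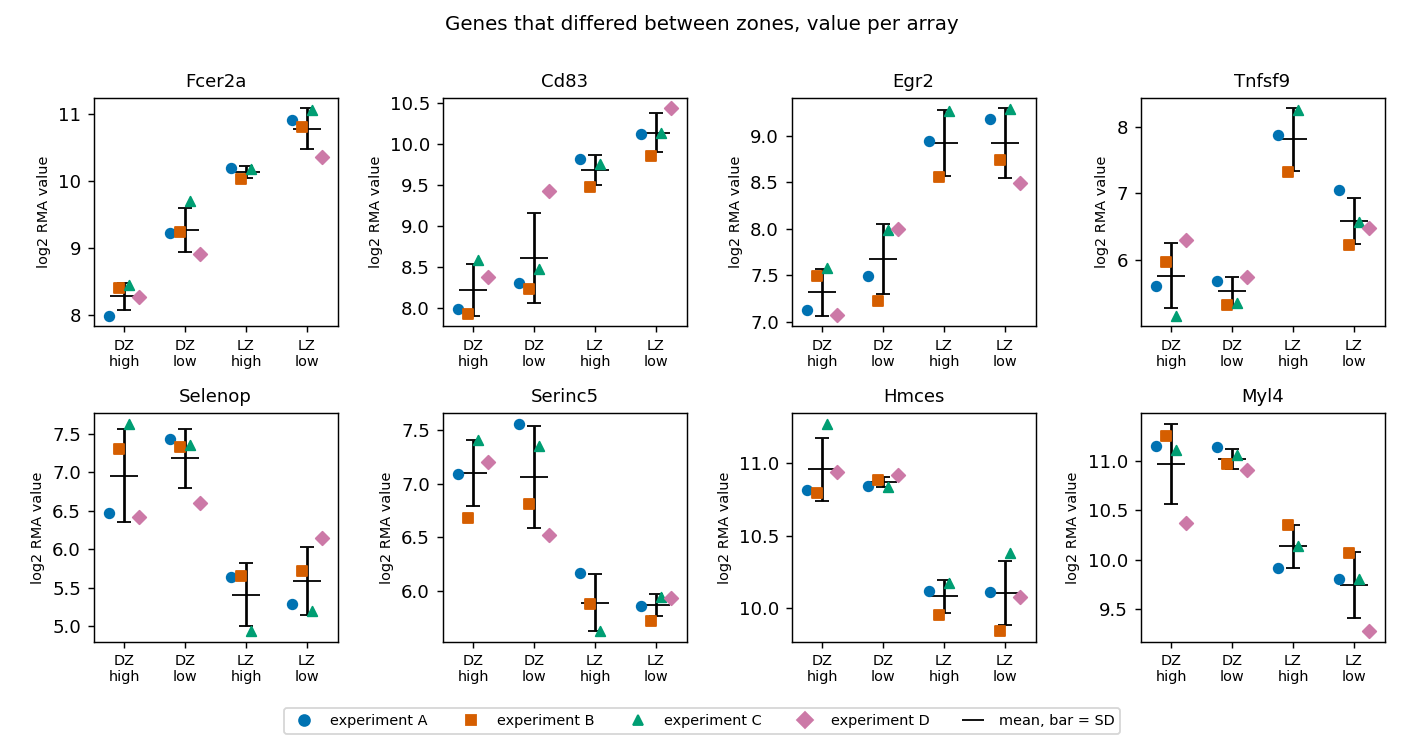
Log2 RMA value (vertical axis) of 8 genes that differed between zones, for each array of the 4 groups (horizontal axis), with symbols for experiments A to D, and the group mean and SD as black bars. Fcer2a, Cd83, Egr2 and Tnfsf9 were higher in light zone (LZ) arrays, by 1.43 to 1.69 on the log2 scale, and Selenop, Serinc5, Hmces and Myl4 were higher in dark zone (DZ) arrays.

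Among the gene lists fixed in advance, the light zone genes rose together between zones: 28 of 32 members lay above 0, with a median of 0.48. Of these, 5 passed over all genes and 19 when adjusted over the list alone. The list passed camera (adjusted p = 1.41e-34) also with an estimated correlation (adjusted p = 0.00107). Besides Cd83 and Egr2 these included Cd40 at 0.65 ± 0.14, Ccr6 at 0.52 ± 0.10 and Birc3 at 0.74 ± 0.17. NF-kappaB and CD40 targets rose as a list, with a median of 0.33 over 36 genes (adjusted p = 0.0132 with an estimated correlation). Over all genes 2 members passed, and 7 adjusted over the list alone. Cholesterol biosynthesis genes lay above 0 in 23 of 24 cases with a median of 0.43 (adjusted p = 0.0309 with an estimated correlation). Over all genes 0 of them passed in limma, and 7 adjusted over the list alone, among them Fdft1 at 0.60 ± 0.14, Dhcr7 at 0.44 ± 0.10 and Insig1 at 0.52 ± 0.13. The list of T cell contact and costimulation genes rose with a median of 0.22, or 0.14 without LZ_high replicate 1, 1 member passing over all genes and 6 adjusted over the list alone (adjusted p = 0.0309 with an estimated correlation). MHC class II presentation genes had a median of 0.32, with 17 of 19 members above 0 and Ifi30 at 0.97 ± 0.22 the only one to pass adjusted over the list alone. Their call was lost with an estimated correlation (adjusted p = 0.131) and kept when the experiment block was added (adjusted p = 0.0273).

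The dark zone genes fell as a list in light zone cells, with 14 of 17 below 0 and a median of -0.24 (adjusted p = 0.0077 with an estimated correlation). Over all genes 0 passed in limma, and 4 adjusted over the list alone, including Polh, the translesion polymerase eta, at -0.83 ± 0.17, Cd93 at -0.72 ± 0.16 and Cdc25b at -0.64 ± 0.16. Genes of G2/M and mitosis lay below 0 in 50 of 54 cases, with a median of -0.31. Their median within experiments was 0.00515, -0.185 and -0.299 among high-affinity cells (A to C). Among low-affinity cells (A to D) it was -0.824, -0.265, -0.462 and -0.952. Over all genes 0 passed in limma, and 7 passed adjusted over the list alone, such as Cdc20 at -0.81 ± 0.17, Cenpa at -0.75 ± 0.17 and Ccnb2 at -1.02 ± 0.29. That list passed the preset correlation and not an estimated one (adjusted p = 0.203 with an estimated correlation, or 0.0201 with the experiment block too), and its median was -0.16 without LZ_low replicate 3. Plasma cell genes lay below 0 in 38 of 52 cases with a median of -0.13 (adjusted p = 0.0382 with an estimated correlation) and below 0 in 6 of 7 pairs. Within experiments the median was -0.207, -0.29 and -0.191 among high-affinity cells (A to C) and -0.121, -0.00815, -0.0517 and 0.051 among low-affinity cells (A to D). The level of the list was 0.165 in DZ_high arrays and -0.0511, -0.0354 and -0.0688 in DZ_low, LZ_high and LZ_low arrays. Adjusted over the list alone, 7 were lower, including Jchain at -1.05 ± 0.29 and Txndc11 at -0.79 ± 0.16, and 3 were higher, including Irf4 at 0.74 ± 0.17. In all, 19 of 33 lists passed camera, 14 higher and 5 lower, and 6 with an estimated correlation, or 9 with the experiment block too. Neutrophil markers had a median of 0.09 between zones (adjusted p = 0.574, or 0.00269 with the experiment block), and T cell markers one of 0.03, with a test that pointed the other way (adjusted p = 0.94). Myeloid markers had one of 0.05 (adjusted p = 0.168, or 0.00346 with the block). Other splits of the arrays between zones gave as many lists in 10 of 100 cases, the real split included. Several of these single genes passed over all genes with the experiment block, in which the forms of code B are merged. Among the higher were Cd40 (adjusted p = 0.0376), Ccr6 (0.0161), Fdft1 (0.0356), Insig1 (0.0325) and Ifi30 (0.0171). Among the lower were Polh (adjusted p = 0.00103), Cd93 (0.0161), Cdc20 (0.0274), Cenpa (0.0172), Ccnb2 (0.0422) and Jchain (0.0272). Without the 2 low-affinity arrays of experiment D, plasma cell, cholesterol and T cell contact genes no longer passed with an estimated correlation (adjusted p = 0.0832, 0.0635 and 0.0832).

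Within each affinity, the zones were compared separately. Among high-affinity cells, 3 genes were higher in the light zone in limma: Tnfsf9 by 2.05 ± 0.28, Fcer2a by 1.86 ± 0.19 and the sort marker Cd86 by 1.33 ± 0.16. Among low-affinity cells, 2 were higher, Aldoc by 1.75 ± 0.24 and Fcer2a by 1.52 ± 0.18. With the experiment code as a block, 11 genes passed among high-affinity cells, 7 higher and 4 lower, and 30 among low-affinity cells, 17 higher and 13 lower. With code B kept as written, in a block that differs between the zones, these counts were 1 and 11. The high-affinity count was 1 without DZ_high replicate 1, 2 or 3 or LZ_high replicate 1 or 4. The low-affinity count was 0 without DZ_low replicate 1 or 2 or LZ_low replicate 2 or 4, 1 without DZ_high replicate 2 or LZ_high replicate 2 or 4, and 4 without DZ_high replicate 3 or 4, LZ_high replicate 1 or LZ_low replicate 1. Tests of whether the zone difference itself depended on affinity called 0 genes, as given with the interaction.

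The next comparison asked how high-affinity cells differed from low-affinity cells in the light zone. No single gene passed. Limma called 0 of 19938 genes, with 797 at an unadjusted p under 0.05, where chance gives 997 if arrays are independent. Arrays of an experiment deviated together, so a count under 997 is no evidence against an effect of affinity. With the experiment block limma also called 0, with 942 unadjusted. The zone comparisons without a block also lay under 997, at 873 over both affinities, 559 among high-affinity and 703 among low-affinity cells. The G2/M and mitosis genes nevertheless lay above 0 in high-affinity cells in 54 of 54 cases, with a median of 0.75, and 2 passed adjusted over the list alone: Bub1b, a spindle checkpoint kinase gene, at 0.85 ± 0.22 and the cyclin gene Ccna2 at 0.66 ± 0.17. The list passed camera (adjusted p = 2.28e-24) and lost its call at adjusted p = 0.0843 with an estimated correlation, while with the experiment block too it passed (adjusted p = 0.0345). Without LZ_low replicate 3 its median was 0.43. Within experiments A, B and C the median was 0.61, 0.47 and 0.30. Of the 35 splits of the 7 light zone arrays, the real one included, 4 gave a median as large. Genes of MYC targets and ribosome biogenesis, with 50 of 57 above 0 and a median of 0.34, passed in the same way (adjusted p = 0.0843 with an estimated correlation, or 0.0398 with the block too). Genes of G1/S and DNA replication had a median of 0.29 (adjusted p = 0.149 with an estimated correlation), or 0.44 without LZ_low replicate 4. Theirs was 0.21, 0.41 and -0.01 within experiments A, B and C, so above 0 in 2 of 3 pairs. Examples were Tyms at 0.85 ± 0.21 and Ccne2 at 1.40 ± 0.43. T cell contact and costimulation genes fell as a list, with 22 of 30 below 0 and a median of -0.28 (adjusted p = 0.0843 with an estimated correlation, or 0.022 with the block too). Adjusted over that list alone, Icam2 was lower at -0.50 and Tnfsf9 higher at 1.23 ± 0.28, and neither passed over all genes (adjusted p = 1).

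Memory and quiescence genes fell in high-affinity light zone cells, with 31 of 34 below 0 and a median of -0.53, and this was the 1 list to keep its call with an estimated correlation and no block (adjusted p = 0.0459). Its median was -0.37, -0.29 and -0.50 within experiments A, B and C, and 2 of the 35 splits gave one as large. Adjusted over the list alone, 1 member passed, the chemokine receptor gene Ccr6 at -0.79 ± 0.14; over all genes 0 did in limma. Cmah at -1.12 ± 0.35 and Pecam1 at -0.73 ± 0.21 were lower in 3 of 3 pairs. B cell receptor signalling components, with 34 of 39 below 0, had a median of -0.32 (adjusted p = 0.0587 with an estimated correlation, or 0.0309 with the block too), and B cell identity genes one of -0.25 (adjusted p = 0.0843 with an estimated correlation). Naive and marginal zone B cell genes had one of -0.35 (adjusted p = 0.0805 with an estimated correlation, or 0.00827 with the block too). MHC class II genes had one of -0.29 (adjusted p = 0.234 with an estimated correlation), or -0.19 without LZ_high replicate 2. Single values were -0.74 ± 0.24 for the kinase gene Syk, -0.71 ± 0.22 for Ciita, which controls MHC class II genes, -0.97 ± 0.40 for the interleukin receptor gene Il4ra and -0.65 ± 0.19 for Fcer2a. In all, 20 of 33 lists passed, 6 higher and 14 lower, and 1 with an estimated correlation, or 7 with the block too. Of the 35 splits of these arrays, 5 gave as many. Among the 14 were neutrophil markers, with a median of -1.16 (adjusted p = 0.476 with an estimated correlation), and T cell markers, with one of -0.31 (adjusted p = 0.266 with an estimated correlation). So were NK cell markers, with a median of -0.18 (adjusted p = 0.483 with an estimated correlation), and myeloid markers, with one of -0.13 (adjusted p = 0.496 with an estimated correlation). Without LZ_low replicate 3 these medians were -0.12, -0.07, -0.03 and -0.05, and of the 4 lists the T cell markers passed. The NK median was -0.374 without LZ_low replicate 1 and -0.275 without LZ_low replicate 4, and the myeloid median -0.214 without LZ_low replicate 1. Without the 2 low-affinity arrays of experiment D, memory genes had a median of -0.36 (adjusted p = 0.022 with an estimated correlation) and G2/M genes one of 0.43 (adjusted p = 0.119 with an estimated correlation).

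In the dark zone, plasma cell genes rose in high-affinity cells, with 46 of 52 above 0, a median of 0.24 and the same sign in 4 of 4 pairs (adjusted p = 0.00289 with an estimated correlation). Of the 35 splits of the 8 dark zone arrays, 2 gave a median as large. Adjusted over the list alone 4 passed, and 0 over all genes in limma. They were Pdia4 at 1.14 ± 0.30 and Fkbp11 at 0.66 ± 0.18, both of protein folding in the endoplasmic reticulum, Pon3, a paraoxonase gene, at 1.31 ± 0.32, and the adhesion molecule gene Epcam at 0.37 ± 0.11. Prdm1, which encodes the plasma cell regulator Blimp-1, had a value of 0.49 ± 0.16 (adjusted p = 1). Xbp1, another gene of the set fixed in advance, had a value of 0.23 (unadjusted p = 0.389 in limma). Genes of G1/S and DNA replication lay above 0 in 47 of 49 cases with a median of 0.27 (adjusted p = 0.298 with an estimated correlation, or 0.0482 with the experiment block too). Genes of the unfolded protein response had a median of 0.16 (adjusted p = 0.306 with an estimated correlation), and without DZ_low replicate 2 they no longer passed (median 0.0973, adjusted p = 0.0727). Their median was 0.103 without DZ_high replicate 3 and 0.262 without DZ_high replicate 4. B cell identity genes lay below 0 in 32 of 38 cases with a median of -0.16 (adjusted p = 0.298 with an estimated correlation), and one of -0.10 without DZ_high replicate 1 or DZ_low replicate 3. Fcer2a, at -0.99 ± 0.18, was the member to pass adjusted over that list alone, and did not pass over all genes (adjusted p = 1). Limma called 0 genes in this comparison, with 320 at an unadjusted p under 0.05, and 0 with the experiment block, with 566. Of 33 lists 14 passed, 6 higher and 8 lower, and 1 with an estimated correlation, or 3 with the block too. Of 35 splits, 6 gave as many, and without DZ_high replicate 1 the count was 8. Neutrophil markers had a median of -0.05 and a mean of 0.01 (adjusted p = 0.942), and a median of 0.49 without the 2 low-affinity arrays of experiment D (adjusted p = 0.000175). Without those arrays plasma cell genes had a median of 0.22 (adjusted p = 0.076 with an estimated correlation).

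**Figure D2:**
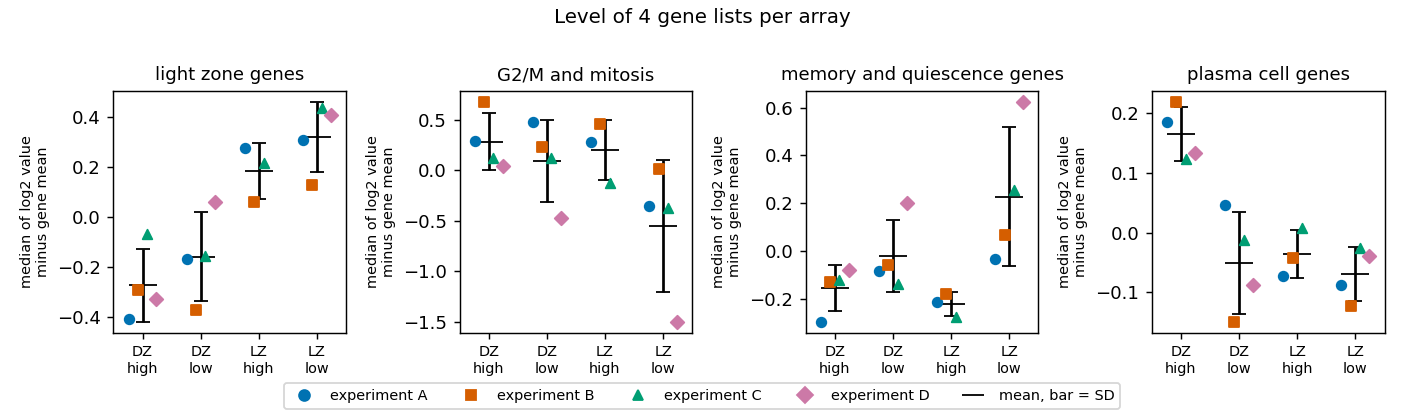
Level of 4 gene lists in each array (vertical axis, median over the members of the log2 value minus the gene's mean over all arrays) by group (horizontal axis), with symbols for experiments A to D, and the group mean and SD as black bars. LZ_low replicate 3, of experiment D, had the lowest G2/M level, at -1.50, and the highest memory and quiescence level, at 0.62.

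Over both zones, high-affinity and low-affinity cells differed at 0 genes in limma, with 857 at an unadjusted p under 0.05 and a lowest adjusted p of 0.348. With the experiment block the count was 0, with 1214 unadjusted. The interaction, which asks whether the effect of affinity depended on the zone, also called 0 genes, with 266 unadjusted, and 0 with the block, with 380. Of the lists, 14 of 33 passed the interaction test, 4 higher and 10 lower, and 0 with an estimated correlation, or 1 with the experiment block too. Without LZ_high replicate 4 the count was 8. G2/M genes were above 0 in 54 of 54 cases, with a median of 0.57 (adjusted p = 0.428 with an estimated correlation), or 0.28 without LZ_low replicate 3. Memory genes had a median of -0.40 (adjusted p = 0.332 with an estimated correlation) and plasma cell genes one of -0.20 (adjusted p = 0.0874 with an estimated correlation, or 0.0319 with the block too). Cmah, at -1.74 ± 0.48, and Ccr6, at -0.71 ± 0.20, passed adjusted over the memory list alone. Neutrophil markers moved in the same comparison, with a median of -0.90 (adjusted p = 0.636 with an estimated correlation), or 0.05 without LZ_low replicate 3. It was -1.52 without DZ_low replicate 3 and -1.45 without LZ_low replicate 1.

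Transcripts of other cell types were high in some arrays, though the gate was for donor B cells. S100a8, a neutrophil gene, was at 11.7 in LZ_low replicate 3 and 10.6 in DZ_low replicate 3, both of experiment D, and between 5.0 and 9.6 elsewhere. The macrophage and neutrophil gene Lyz2 was at 10.7 and 9.0 in those arrays, the killer cell gene Gzma at 10.5 and 8.9, and the T cell gene Cd3e at 8.0 and 6.6. LZ_low replicate 4, of experiment C, had Lyz2 at 8.2 and Cd3d at 7.3. In DZ_high replicate 4, also of experiment D, Lyz2 was at 7.1 and Cd3e at 5.6. Dendritic cell, stromal and erythroid marker lists did not pass between zones (adjusted p = 0.103, 0.764 and 0.94), except the dendritic cell list with the experiment block (adjusted p = 0.0336). They did not pass either between affinities in the light zone (adjusted p = 0.225, 0.719 and 0.708) or in the dark zone (adjusted p = 0.923, 0.25 and 0.807). Genes of the stress and dissociation list, which covers handling, lay higher in light zone cells by medians of 0.0022 to 0.133 within experiments.

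**Figure D3:**
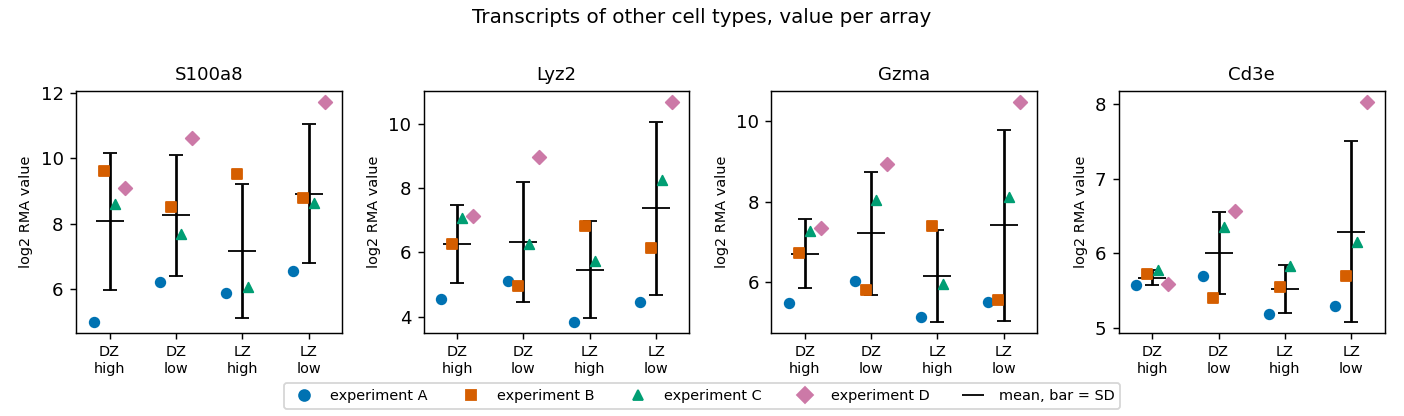
Log2 RMA value (vertical axis) of S100a8, Lyz2, Gzma and Cd3e in each array of the 4 groups (horizontal axis), with symbols for experiments A to D, and the group mean and SD as black bars. The highest value of each gene was that of LZ_low replicate 3, such as 11.7 for S100a8 and 8.0 for Cd3e.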

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

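The splits of the arrays were planned for the gene counts between zones, the counts of lists and the medians of 3 lists, while the splits for the counts of 0 genes and all tests of other cells were chosen after the result was seen. For the genes that differed between zones, under 0.05 of the splits gave as many as the real one. This does not exclude chance, because arrays of an experiment deviated together, so the splits are not alike. Within each affinity, splits that part every pair of an experiment are too few for a share under 0.05. Over both affinities more of them exist than were drawn, and a test on all of them was not run. Of 100 splits drawn, 2, the real one included, gave as many as 31. Of 35 splits, 1 gave as many as the 3 among high-affinity cells and the 2 among low-affinity cells, where the highest other was 0. The 31 and the 3 include Cd86, a gene of the sort markers. Between zones over both affinities the highest other split gave 736 genes, which points to a structure of the samples. It set low-affinity arrays of experiments A and B against those of C and D, and the count with the experiment block was 90. Splits that part every pair numbered 4 of the 100 drawn over both affinities and 8 within each, and the highest other among them was 0. Chance cannot be excluded for the counts of lists either. These were 19 between zones (10 of 100 splits, highest other 23) and 20 for affinity in the light zone (5 of 35, highest other 21). They were 14 in the dark zone (6 of 35, highest other 18) and 14 for the interaction (35 of 100, highest other 25). Every split gives at least 0 genes, so splits decide nothing about the counts of 0. The number was 35 of 35 for affinity in the light zone, with a highest other of 64 from the split of experiments A and B against C and D. It was 35 of 35 in the dark zone, with a highest other of 1, 100 of 100 over both zones, with a highest other of 1, and 100 of 100 for the interaction, with a highest other of 536.

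Memory and quiescence genes had a median of -0.53 for affinity in the light zone, and chance cannot be excluded, since 2 of 35 splits gave a size of at least 0.53, the highest other being 0.55. Of the 8 splits that part every pair of an experiment the real one was the largest (highest other 0.336), and 8 are too few for a share under 0.05, here and for the next lists. RNA of other cells in the 2 low-affinity arrays of experiment D is argued against as the whole cause, because the median was -0.36 without them. That fit keeps LZ_low replicate 4 of experiment C, which also carried transcripts of other cells. The level of the list was 0.62 and 0.255 in LZ_low replicates 3 and 4, and -0.033 and 0.066 in replicates 1 and 2. In experiments A and B, which hold neither of the former, the median was -0.37 and -0.287. Resting B cells within the low-affinity light zone gate stay open. They would lower germinal centre genes there, whereas the median of that list, high minus low affinity, was -0.14, -0.08 and -0.24 in experiments A to C, the opposite direction; members went both ways, with an upper quartile of up to 0.11, so this does not exclude them.

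G2/M and mitosis genes had a median of 0.75 for affinity in the light zone, and chance cannot be excluded, since 4 of 35 splits gave one as large, the highest other being 0.83; among the 8 that part every pair the real one was the largest (highest other 0.575). Without the 2 low-affinity arrays of experiment D the median was 0.43, which argues against RNA of other cells there as the whole cause and leaves open that it enlarged the difference. Dark zone cells within the high-affinity light zone gate stay open, as do affinity and chance: in experiments A, B and C zone genes lay at most a share of 0.202, 0.245 and 0.3 of the way to the dark zone level and G2/M genes 0.71, 1.08 and 0.407. The lowest gap, 0.107, is below the SD of the gap between experiments (0.363); each share rests on 1 array per group, and in B the dark zone arrays carry a differently written code.

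Plasma cell genes had a median of 0.24 for affinity in the dark zone, and chance cannot be excluded, since 2 of 35 splits gave one as large, the highest other being 0.26; among the 8 that part every pair the real one was the largest (highest other 0.164). Without the 2 low-affinity arrays of experiment D the median was 0.22, which argues against RNA of other cells there as the whole cause. The list then lost its call with an estimated correlation. Neutrophil markers then lay higher in high-affinity cells, so that fit is not free of RNA of other cells. Plasmablasts within the high-affinity dark zone gate cannot be told apart from a change within germinal centre cells. The plasmablast genes tested had a median of 0.24. Jchain was at 0.77, Tnfrsf17 at 0.26, Sdc1 at 0.25, Xbp1 at 0.23, Slamf7 at 0.03 and Mzb1 at -0.12. Their unadjusted p in limma ran from 0.0715 to 0.901, which keeps it open. By the rule set, only a rise of all of them at p under 0.05, or a negative median, would have decided.

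In 10 of 357 groups tested, 1 array stood apart from the others of its group. LZ_high, with 3 arrays, was not tested in this way. Its replicate 4 had a mean correlation of 0.9518 with all other arrays, against 0.9717 and 0.9757 for its replicates 1 and 2. For LZ_low replicate 3 it was 0.9407. Chance flags about 1 in 20 groups. On the log2 scale, Batf was at 7.65 in DZ_low replicate 1 (mean of the others 7.23), Selenop at 6.60 in DZ_low replicate 3 (7.37), Myl4 at 10.37 in DZ_high replicate 4 (11.17) and Foxp1 at 7.61 in LZ_low replicate 4 (7.94). Wdr75 was at 7.11 in LZ_low replicate 3 (8.86), Tfrc at 8.20 in DZ_high replicate 1 (8.45), Il6st at 6.67 in LZ_low replicate 3 (6.10) and Pole2 at 8.75 in DZ_high replicate 3 (8.15). The level of the germinal centre list was 0.18 in DZ_high replicate 3 (-0.02), and that of the myeloid list 0.33 in DZ_low replicate 3 (-0.17).

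In 14 lists the effect of affinity differed between the zones in camera at its preset correlation, and in 0 with an estimated correlation. The median differences, light zone minus dark zone, were 0.57 for G2/M, 0.31 for histone, 0.23 for MYC target and 0.17 for oxidative phosphorylation genes. They were -0.40 for memory, -0.20 for plasma cell, -0.12 for unfolded protein response, -0.18 for B cell receptor signalling, -0.22 for interferon-stimulated and -0.21 for migration genes. For markers of other cells they were -0.21 for T cells, -0.19 for myeloid cells, -0.90 for neutrophils and -0.33 for NK cells. With the experiment block the myeloid and NK lists no longer passed (adjusted p = 0.0886 and 0.133). With 1 array left out, 5 of the 14 passed in 15 of 15 fits: G2/M (medians 0.283 to 0.719), MYC target (0.104 to 0.322), memory (-0.451 to -0.271), plasma cell (-0.272 to -0.157) and migration genes (-0.301 to -0.124). Genes of oxidative phosphorylation (0.03, without DZ_high replicate 4, to 0.282), receptor signalling (-0.27 to -0.114) and interferon-stimulated genes (-0.278 to -0.149) passed in 14 of 15 fits. Histone genes passed in 7 fits, with medians from -0.106 without LZ_high replicate 4 to 0.613 without LZ_high replicate 1. Genes of the unfolded protein response passed in 8, with medians from -0.193 to -0.00675 without DZ_low replicate 2. Of the other cells, T cell and neutrophil markers passed in 13 fits each, NK in 10 and myeloid markers in 5. Without LZ_low replicate 3 none of these 4 passed, at medians of -0.00316 for T cells, 0.0506 for neutrophils, -0.146 for NK and -0.0692 for myeloid cells. The neutrophil median was -1.52 without DZ_low replicate 3, the T cell median -0.345 without LZ_low replicate 1 and the myeloid median -0.306 without LZ_low replicate 2.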

How the results depend on the processing

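Leaving out the 2 low-affinity arrays of experiment D, or all of that experiment with or without the block, was chosen after the result was seen; the other alternatives were planned. Of values per gene with 1 array left out, 2152 kept their direction and side of the threshold, 49 changed sign without passing in either fit, 85 no longer passed and 9 newly passed. Under the other alternatives these counts were 2080, 28, 30 and 77. For gene lists, by the direction of their test, they were 1653, 162, 106 and 56, with 3 reversed, with 1 array left out. Under the others they were 1581, 137, 135 and 55, with 6 reversed. In all, 376 of 8404 values changed sign without passing. Where a count moved, the cause was not tested.

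The count of genes between zones was 49 (23 higher, 26 lower) after a further quantile normalization and 68 (36 and 32) with array weights. Among high-affinity cells it was 7 after quantile normalization, 7 over every probe set, 5 with array weights, 1 with only the groups compared, 5 without the 2 D arrays and 6 without experiment D. Among low-affinity cells it was 11 after quantile normalization, 1 over every probe set, 8 with the mean of probe sets, 6 with trend and robust variance, 16 with array weights, 0 with only the groups compared and 4 without experiment D. For affinity over both zones it was 2 after quantile normalization, 1 with array weights and 1 without the 2 D arrays. In the dark zone it was 3 over every probe set.

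With the experiment code as a replicate block, the count between zones was 90, with 11 among high-affinity and 30 among low-affinity cells. With the title number as the block it was 83, 7 and 18, and 1 for affinity over both zones. With the code as written it was 1 among high-affinity and 11 among low-affinity cells. With the code as a random block (correlation 0.175) it was 78, 6 and 18. Without experiment D and with the block it was 136, 9 and 24. The random block was not run for gene lists.

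With an estimated correlation between genes, the lists passing were 6 between zones, 1 for affinity in the light zone, 1 in the dark zone and 0 for the interaction. Interaction lists were 8 with array weights and 9 without experiment D.

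With 1 array left out, the count was 18 to 37 between zones, 1 to 4 among high-affinity and 0 to 4 among low-affinity cells, and 0 for each affinity comparison and the interaction. Lists passing were 15 to 22 between zones, 18 to 20 for affinity in the light zone, 8 to 17 in the dark zone and 8 to 16 for the interaction.

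For affinity in the dark zone, the G2/M median reversed to -0.0291 and the neutrophil median to 0.494, both without DZ_low replicate 3 and without the 2 D arrays. With 1 array left out they ranged from -0.0291 to 0.252 and from -0.311 to 0.494. Without experiment D, with or without the block, the neutrophil median was 0.23, and the histone list, at a median of 0.50, turned its test direction. In the light zone the somatic hypermutation and DNA repair list turned its test direction without LZ_high replicate 1, at a median of 0.0806, in a range of 0.0806 to 0.403. Arrays have no read depth; dim probe sets near background limit what can be seen.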

Other observations

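The genes named here were chosen after their values were seen, and no test was added for them; the lists were fixed in advance. Between zones, immediate early genes induced by the B cell receptor had a median of 0.14 and passed camera (adjusted p = 1.36e-05; adjusted p = 0.281 with an estimated correlation). The median was 0.0951 without DZ_low replicate 1, 0.0705 without DZ_low replicate 2, 0.0919 without LZ_high replicate 4 and 0.0769 without LZ_low replicate 3. Besides Egr2, their members Egr1 at 0.99 ± 0.26 (over all genes, adjusted p = 0.265, or 0.0274 with the experiment block) and Myc at 0.72 ± 0.21 passed adjusted over the list alone, as did Atf3 in the other direction at -0.37. B cell receptor signalling components had a median of 0.10 (adjusted p = 0.0873 with an estimated correlation), which leaving out DZ_high replicate 2 or 3, DZ_low replicate 1, 2 or 3 or LZ_low replicate 2 moved to between 0.0635 and 0.175, with 6 members passing adjusted over the list alone, among them the complement receptor gene Cr2 at 0.89 ± 0.19. The germinal centre list showed no common shift, with 11 members above and 12 below 0 (adjusted p = 0.999). Within it Cd83 and Cxcr5, at 0.79, were higher adjusted over the list alone, and Gcsam at -0.82, Neil1 at -0.70 and Hmces were lower. Among apoptosis regulators, which did not pass as a list (adjusted p = 0.101), the survival genes Bcl2l1 at 0.64 and Birc3 at 0.74 and the proapoptotic gene Bcl2l11 at -0.61 passed adjusted over the list alone.

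For affinity in the light zone, oxidative phosphorylation genes had a median of 0.15 with 45 of 54 above 0 (adjusted p = 4.89e-06; adjusted p = 0.401 with an estimated correlation), and one of 0.238 without LZ_high replicate 1. Migration and positioning receptors had a median of -0.35 with 28 of 32 below 0 (adjusted p = 0.0587 with an estimated correlation, or 0.00827 with the experiment block too), and Ccr6 passed adjusted over that list alone. Cd2, in the T cell marker list, was at -1.04 ± 0.20 and the only member to pass adjusted over the list alone. Of the 20 T cell markers, 5 lay above the array median in the 13 arrays other than the 2 low-affinity ones of experiment D, and 3 are in another list; of the 14 neutrophil markers these counts were 4 and 1, of 25 myeloid markers 8 and 1, and of 15 NK cell markers 6 and 0.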
